A study of Arabidopsis thaliana with 16 samples.

How the data were processed

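Whole seedlings of Arabidopsis thaliana ecotype Col-0 were 20 days old, had grown with 12 h of light per day, and were either held at 4 °C for 24 h or left untreated, per the labels' protocols. The 16 samples formed 6 groups. There were 3 cold and 3 control lists of peaks from m6A immunoprecipitation (MeRIP), in which an antibody enriches fragments of mRNA that carry N6-methyladenosine. There were 3 cold and 3 control mRNA sequencing libraries, and 2 cold and 2 control libraries of polysomal RNA, the RNA recovered with ribosomes. Per the labels' protocols, mRNA was fragmented to about 100 nt before immunoprecipitation and libraries were made with a stranded kit. The time of day of collection, the light during the cold treatment and the polysome isolation were not given in the sources used here. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which can be technical.

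The mRNA and polysome files hold read counts per gene that the authors deposited, made with STAR and HTSeq on the TAIR10 build per the submitters' processing notes, which give no versions. The strand setting and the annotation release behind the counts were not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Reads with more than 1 alignment were tallied apart and given to no gene, so counts of near-identical copies (such as COR15A and COR15B, KIN1 and KIN2, the CBF cluster, LHCB1 and RBCS genes) rest on the reads that told the copies apart and are uncertain. The peak files hold, for each peak, a score, a fold enrichment (a ratio over the caller's background), a −log10 p and a −log10 q, all as the authors deposited them; peaks were called with MACS2 per the submitters' processing notes. Each list came from 1 library, with no pooling. Peak names end in plus or minus, so calls were made per strand. Each deposited list held peaks down to an unadjusted p of about 0.05, with no limit on q. On average 31.5% of cold and 33.0% of control peaks had a q of at most 0.05. The fold of a peak is the authors' value and was used only within its own list.

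The files held 34262 features, of which 32548 matched a locus of the RefSeq annotation of TAIR10.1. Another 1429 were non-coding RNAs under other names, and 285 were chloroplast or mitochondrial genes. Library sizes and tests used gene counts only. Gene counts were 25.8%, 31.2% and 6.60% of all tallied reads in cold mRNA replicates 1, 2 and 3, and 26.0%, 25.7% and 27.0% in the control mRNA libraries. They were 92.8% to 93.8% in the polysome libraries. The remaining reads had no unique alignment, lay outside genes or were ambiguous. No replicate pair agreed within sampling noise: the chi-square per degree of freedom between replicates was 11.95 or higher.

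Groups were compared with edgeR 4.0.16 (quasi-likelihood F test, robust fit, TMM normalisation, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The mRNA comparison used its 6 libraries and the polysome comparison its 4, which leave 2 residual degrees of freedom. The interaction was fitted over all 10 libraries as the cold-to-control change in polysomal RNA minus the change in mRNA, and is called translational efficiency (TE). TMM factors for this fit were computed over the 10 libraries together, and the median TE of genes with a mean log2 CPM of at least 1 was −0.041. Normalised read counts are CPM, gene counts scaled by library size with TMM factors over the 10 libraries, given as mean ± SD; fold changes are given as log2 with SE. Ratios of polysomal to total mRNA within a condition used log2(CPM + 0.5).

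Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over lists, and again with an estimated correlation and with fry. The 16 lists held 318 genes: cold regulators, COR and LEA proteins, sugar, starch and proline, lipid remodelling, flavonoid and anthocyanin, photosynthesis, circadian clock, m6A writers, erasers and readers, ribosome biogenesis, cytosolic ribosomal proteins, cold RNA-binding proteins, abscisic acid, heat shock and chaperones, cell expansion and growth hormones, root markers, and floral organ markers. Lists, tests, the rule for named genes and the alternatives were chosen before the data were examined, except where stated. The rule names 17 genes always (CBF1, CBF2, CBF3, COR15A, RD29A, KIN1, MTA, MTB, FIP37, VIR, HAKAI, ALKBH9B, ALKBH10B, ECT2, ECT3, ECT4 and DGAT1). Per comparison it adds the 8 largest rises and 8 largest falls among nuclear coding genes past the threshold with a mean log2 CPM of at least 4, with no overlap between groups for mRNA and polysomes. Per list it adds up to 2 rises and 2 falls, or the 2 members of lowest p. For m6A it adds up to 5 gained and 5 lost genes with at least 20 CPM in both mRNA groups. A gene without a symbol is given by its locus identifier.

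Peak summits were placed on 1 representative transcript per gene of TAIR10.1. About 96% of calls named plus lay in exons of minus-strand genes and the reverse (95.8% to 97.4% in the 6 lists), so the gene strand was taken as opposite to the name. A gene counted as gained with a summit in an exon in all 3 cold lists and in 0 of 3 control lists, and as lost in the reverse case, among 14046 genes with at least 5 CPM in both mRNA groups. Those 14046 were drawn from all counted features, whereas peaks were placed on nuclear genes only. Chloroplast, mitochondrial and other-named non-coding features above the floor thus counted as without a peak, whatever peaks they carried. Values per list were compared with exact two-sided permutation tests, whose smallest p with 3 against 3 is 0.1. Median changes of gene sets were placed among 10000 random sets matched on expression in 20 bins. Motif shares were counted within 50 nt of summits and of random exonic positions. Peak counts depend on the depth of each list, which was not given in the sources used here.

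Steps were tested on simulated data. Of 100 genes changed 2-fold and 100 changed 4-fold among 19074 simulated mRNA genes, 34% and 92% were recovered. The shares were 5% and 74% of the same numbers for polysomes (19042 genes) and 1% and 49% for TE (19822 genes). Unchanged genes called beside these numbered 8 for mRNA, 21 for polysomes and 5 for TE. In this single run their share of all calls was above the nominal 0.05, by far the most for polysomes. In the list test, 1 of 1 shifted lists and 0 others were called. Genes were drawn independently there, so the preset correlation of 0.01 was not tested. In the peak step, 50 of 50 planted gained and 50 of 50 planted lost genes were found among 13531, beside 26 others. The planted genes met the rule by design, so their recovery checked the code only. Peaks of the other genes were drawn independently for each gene and list, unlike real detection, which depends on expression. Alternatives were DESeq2 1.42.0, RLE size factors, library totals, other count filters, organelle genes left out, voom, 1 fit of all count libraries, a block on replicate number, each replicate left out, stricter peaks, equal numbers of top peaks and other overlap rules. Added after the data were seen were a q limit of 0.05, exons on either strand, motif checks on stronger peaks and against the same transcript part, and list tests and polysome to mRNA ratios of clock and dark-inducible genes with each replicate left out.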

Results

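The series asks what part N6-methyladenosine (m6A), the most common internal mark of mRNA, plays in the response of Arabidopsis seedlings to cold. Whole Col-0 seedlings, 20 days old, were held at 4 °C for 24 h or left untreated. For each condition there were 3 lists of m6A peaks, 3 mRNA libraries and 2 libraries of polysomal RNA. Gene counts per library, given in units of 1e+06, were 10.2, 10.4 and 3.28 for cold mRNA and 8.43, 10.97 and 10.9 for control mRNA. They were 22.2 and 13.0 for cold polysomes and 20.5 and 21.5 for control polysomes. Cold mRNA replicate 3 stood apart. It had 82.2% of its reads without a unique alignment, against 61.9% to 66.3% in the other mRNA libraries, and 22.1% of its gene counts came from chloroplast and mitochondrial genes, against 6.28% to 8.70%. Its 20 most abundant genes took 23.8% of its gene counts, against 9.66% to 11.9% in the other mRNA libraries. Cold m6A list 3 was also the shortest, with 15383 peaks against 23174 to 27310.

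Among genes with a mean log2 CPM of at least 4, the largest rises in total mRNA included COR genes and clock genes. COR15B, a chloroplast protein that protects membranes during freezing, rose from 6.32 ± 0.668 to 1497 ± 121 CPM (SD, n = 3 per group), a log2 fold change of 7.81 (SE 0.21, adjusted p = 9.79e-07, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Its near-identical neighbour COR15A rose by 6.60 (SE 0.495) on the log2 scale, the dehydration-responsive RD29A by 3.37 (SE 0.214) and the small hydrophilic protein gene KIN1 by 5.26 (SE 0.275). COR27 and COR28 encode cold-induced proteins that act in the circadian clock. COR27 rose by 8.30 (SE 0.457). COR28 had 972 reads in the cold and 3 in the control libraries, a depth-scaled ratio of 466 with a 95% interval of 159 to 2.26e+03 that covers counting error only. FKF1, a blue-light receptor of the photoperiodic flowering pathway, rose by 7.25 (SE 0.611), the clock repressor PRR5 by 7.04 (SE 0.36), the Rubisco assembly chaperone RbcX1 by 6.22 (SE 0.277) and AT2G33830, a dormancy- and auxin-associated family member, by 6.06 (SE 0.511). Among the largest falls under the same limit were the sulfur-deficiency gene ATSDI1 at −3.90 (SE 0.438), the cis-prenyltransferase gene cPT4 at −3.52 (SE 0.453), SIS at −3.40 (SE 0.611) and the remorin AT2G41870 at −3.11 (SE 0.6). A pair of aquaporins also fell, RD28 of the plasma membrane at −3.50 (SE 0.299) and TIP2;2 of the vacuole at −3.30 (SE 0.289). The caleosin RD20 at −3.79 (SE 0.892) and the sugar transporter gene SAG29 at −3.31 (SE 0.89) had adjusted p-values of 0.0323 and 0.045, and both lost the call when any of 5 libraries was left out.

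In all, 2586 genes rose and 2363 fell among 19261 tested for mRNA, of which 1206 and 1325 changed at least 2-fold. Direction depended on scaling. With library totals in place of TMM factors the median log2 change of genes with a mean log2 CPM of at least 1 was −0.173. Under that scaling 1361 genes rose and 2872 fell, and the higher share was 32.15% in place of 52.25%. In a fit of all 10 count libraries it was 60.75%. The count of rises was 1585 without cold replicate 1, 1604 without cold replicate 2 and 1424 without control replicate 2, and the count of falls without these was 1283, 1204 and 1148. Without cold mRNA replicate 3, the library with the low share of gene reads, 2626 rose and 2218 fell.

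The COR and LEA list, of cold-induced and late embryogenesis proteins that protect cells from freezing and drying, rose as a group. Of its 23 measured members 16 rose and 0 fell, and the count was 16 when adjusted over the list alone (camera adjusted p = 4.61e-31; adjusted p = 0.0378 with an estimated correlation). Among 21 measured cold regulators 6 rose and 2 fell, also 6 and 2 adjusted over the list alone (camera adjusted p = 4.33e-06; adjusted p = 0.145 with an estimated correlation). The falls were MYB15, a repressor of CBF genes, at −2.49 (SE 0.59), and the calmodulin-binding activator CAMTA1 at −0.60 (SE 0.18). The CBF transcription factors, which act in the first hours of cold, did not pass in mRNA. CBF2 measured 2.07 (SE 1.08, adjusted p = 0.213) and CBF3 1.77 (SE 0.848, adjusted p = 0.167), and CBF1 was too low to test, at 0.408 ± 0.148 CPM in cold and 0.568 ± 0.728 in control libraries. Without control mRNA replicate 2, CBF2 passed. Among 22 sugar, starch and proline genes 9 rose and 3 fell, or 11 and 4 adjusted over the list alone (camera adjusted p = 6.74e-04; adjusted p = 0.078 with an estimated correlation). GOLS3, which makes galactinol for raffinose, rose by 5.23 (SE 0.626) and the starch-degrading BAM3 by 2.91 (SE 0.238), whereas GOLS2 and BAM1 changed by −4.35 (SE 0.4) and −1.45 (SE 0.179).

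Nearly all listed ribosome biogenesis genes rose, and part of the ribosomal protein genes. Of 22 ribosome biogenesis genes 21 rose and 0 fell, with the same 21 adjusted over the list alone, among them the rRNA-modifying FIB2 by 1.82 (SE 0.176) and the ribosome assembly factor gene BRX1-1 by 1.48 (SE 0.222). Camera gave an adjusted p of 6.25e-12 for this list, and an adjusted p = 0.207 with an estimated correlation. Of 23 cytosolic ribosomal protein genes 10 rose and 0 fell, or 15 and 0 adjusted over the list alone, with RPL9B at 0.87 (SE 0.148) and RPL3A at 0.69 (SE 0.151) (camera adjusted p = 3.23e-04; adjusted p = 0.482 with an estimated correlation). With library totals as scaling, 13 of the biogenesis genes and 1 ribosomal protein gene rose. Of 8 RNA-binding proteins linked to cold 3 rose and 0 fell, or 5 and 0 adjusted over the list alone (camera adjusted p = 4.33e-06; adjusted p = 0.0378 with an estimated correlation). The clock-controlled GRP7 went from 60.8 ± 2.59 to 3455 ± 176 CPM, and GRP8 rose by 1.24 (SE 0.216). The call for RPL3A was lost with library totals, without cold replicate 1 and without control replicate 2.

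Clock genes also rose as a group. Of 24 clock genes 10 rose and 2 fell, or 12 and 4 adjusted over the list alone (camera adjusted p = 7.5e-12; adjusted p = 0.0378 with an estimated correlation). The rises were led by FKF1 and PRR5, and the falls were the coactivator gene LNK1 at −0.93 (SE 0.222) and the activator gene RVE8 at −0.79 (SE 0.25). Time of day at collection was not given in the sources used here, and clock transcripts cycle over the day. Median log2 CPM of 11 evening-phased genes minus that of 9 morning-phased genes was −0.43, −0.88 and −0.28 in the cold mRNA libraries and −2.91, −2.94 and −4.24 in the control mRNA libraries. LNK1 lost its call without cold replicate 2 or control replicate 2, and RVE8 without any of 5 libraries.

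Other groups were mixed or fell in mRNA. Of 20 genes of cell expansion and growth hormones 0 rose and 8 fell, 9 adjusted over the list alone (camera adjusted p = 4.67e-04; adjusted p = 0.078 with an estimated correlation). The gibberellin-inactivating GA2OX2 was at −2.44 (SE 0.64) and the growth-promoting factor gene PIF4 at −1.60 (SE 0.245). Of 16 heat shock and chaperone genes 1 rose, DREB2A by 1.67 (SE 0.305), and 3 fell, counts that were the same adjusted over the list alone; HSP17.6II and HSFA2 were at −2.63 (SE 0.53) and −2.34 (SE 0.524). Camera gave this list an adjusted p of 0.0381 and, with an estimated correlation, an adjusted p = 0.221, and its call was lost without cold replicate 1 (0.0637), cold replicate 3 (0.0567) or control replicate 1 (0.0551). Of 20 abscisic acid genes 4 rose and 7 fell, 5 and 8 adjusted over the list alone (camera adjusted p = 0.197, and 0.0358 without control replicate 3). The bZIP factor genes ABF1 and ABI5 rose by 4.999 (SE 0.454) and 2.90 (SE 0.443), and the phosphatase gene HAI1 was at −4.20 (SE 0.795). Lipid remodelling genes split, with 4 rises and 5 falls of 19, also 4 and 5 adjusted over the list alone (camera adjusted p = 0.265, and 0.0387 by fry, which does not compare a list with other genes). DGAT1, which makes triacylglycerol, rose from 3.87 ± 1.33 to 37.5 ± 5.23 CPM, a log2 change of 3.22 (SE 0.273), and the desaturase gene ADS2 rose by 3.12 (SE 0.209), whereas ADS1 was at −1.98 (SE 0.552) and the galactolipid synthase gene DGD1 at −1.09 (SE 0.267).

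Flavonoid and anthocyanin genes also split in mRNA, with 4 rises and 5 falls of 19, or 5 and 6 adjusted over the list alone. The hydroxylase gene F3PH rose by 3.09 (SE 0.33) and chalcone synthase, CHS, by 1.33 (SE 0.223), and the anthocyanin regulator PAP1 and the reductase DFR were at −2.52 (SE 0.688) and −2.48 (SE 0.31). The median of the list was 0.45 and its mean −0.10 (camera adjusted p = 0.476, and 0.0362 without cold replicate 2). Among 26 photosynthesis genes 3 rose and 5 fell, the same adjusted over the list alone, with LHCB1.4 at 1.54 (SE 0.369), LHCB1.3 at 0.74 (SE 0.235), RBCS2B at −1.05 (SE 0.228) and LHCB4.2 at −1.05 (SE 0.258) (camera adjusted p = 0.14). Without cold replicate 3, 2 of them rose and 13 fell (camera adjusted p = 7.68e-04), and with library totals 2 rose and 11 fell. Without cold replicate 3 the falls numbered 2 for the lipid list and 2 for the flavonoid list. Of 16 root markers 0 rose and 1 fell, TIP2;3 at −2.26 (SE 0.648), and 0 passed adjusted over the list alone (camera adjusted p = 0.999); 1 floral organ marker was measured, SEP3, at 0.37 (SE 0.551, adjusted p = 0.648). Each count of 0 by edgeR for these and the other mRNA lists, except the m6A list, was also 0 by DESeq2 and at an unadjusted p under 0.05. Each of the calls of MYB15, CAMTA1, GA2OX2, HSFA2, HAI1, ADS1, DGD1, PAP1, LHCB1.3, LHCB1.4, LHCB4.2, RBCS2B and TIP2;3 was lost when at least 1 of the libraries was left out.

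**Figure D1:**
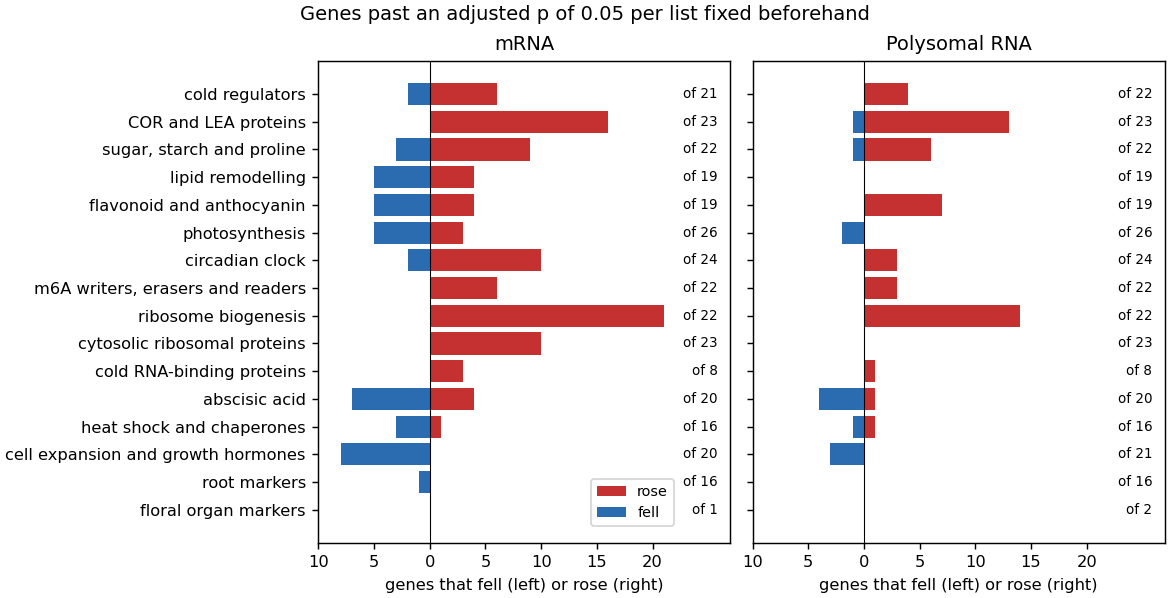
Number of genes past an adjusted p of 0.05 in each gene list, fallen to the left and risen to the right, for mRNA (3 cold against 3 control libraries) and polysomal RNA (2 against 2); the number of measured members stands at the right. Ribosome biogenesis has 21 rises in mRNA and 14 in polysomal RNA, and the COR and LEA list 16 and 13.

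Among 22 measured m6A writers, erasers and readers 6 rose and 0 fell (1 lower at an unadjusted p under 0.05, 0 by DESeq2), the same adjusted over the list alone. The list was not called (camera adjusted p = 0.0756, and 0.0415 without control replicate 3; adjusted p = 0.211 with an estimated correlation). Fry, which does not compare a list with other genes, gave it an adjusted p of 0.00441. The YTH-domain reader ECT4 rose by 1.21 (SE 0.133, adjusted p = 7.70e-04), ECT2, the most abundant of the named readers, by 0.57 (SE 0.141, adjusted p = 0.0193) and ECT3 by 0.66 (SE 0.21, adjusted p = 0.0488). MTB, a subunit of the methyltransferase, rose by 0.82 (SE 0.153, adjusted p = 0.00624) and the AlkB-family gene ALKBH10A by 1.46 (SE 0.379), whereas the catalytic subunit MTA measured 0.31 (SE 0.145, adjusted p = 0.147). The writer partners FIP37, VIR and HAKAI, at 0.23, 0.21 and 0.17, and the demethylases ALKBH9B and ALKBH10B, at −0.66 (SE 0.263) and 0.06 (SE 0.155), did not pass. Under library totals 3 members of the list rose, and ECT2 and ECT3 were not among the calls. ALKBH10A, ECT2 and ECT3 each lost the call without cold replicate 2 and without control replicate 2, ALKBH10A also without cold replicate 1, and ECT3 without 3 other libraries.

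Among genes with a mean log2 CPM of at least 4, the largest rise in polysomal RNA was in GOLS3. It rose from 2.92 ± 0.14 to 542 ± 495 CPM (SD, n = 2 per group), a log2 change of 7.52 (SE 0.873, adjusted p = 0.0201, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The clock-related MYB gene RVE2 rose by 5.30 (SE 0.613), KIN1 by 5.29 (SE 0.362), the dehydrin gene LTI30 by 5.21 (SE 0.639), AT1G16850 by 5.18 (SE 0.395), and RD29A by 4.69 (SE 0.649). The early light-induced protein gene ELIP2 rose by 4.61 (SE 0.725), ADH1 by 4.52 (SE 0.508) and COR15A by 4.21 (SE 0.667). The largest fall under the same limit was in the asparagine synthetase gene ASN1, known to be induced by darkness. It went from 434 ± 112 to 21.1 ± 2.43 CPM (log2 −4.37, SE 0.331, adjusted p = 0.0155) and the senescence-associated SEN1 from 539 ± 340 to 36.9 ± 17.7 (log2 −3.87, SE 0.603). The TRAF-like AT2G32880 was at −4.17 (SE 0.252), the galactosidase BGAL4 at −4.09 (SE 0.412), the lipid-transfer family member AT1G62510 at −4.08 (SE 0.412), AT4G27450 at −3.96 (SE 0.402), the LEA family member AT3G02480 at −3.91 (SE 0.764) and MLP329 at −3.77 (SE 0.557). In total mRNA, ASN1 measured −0.25 (SE 0.448, adjusted p = 0.716) and SEN1 0.03 (SE 0.794, adjusted p = 0.985).

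Of 19239 genes tested in polysomal RNA 744 rose and 760 fell, and 709 and 742 changed at least 2-fold. With 2 libraries per group, the counts depended on single libraries. Without control replicate 1, 141 rose and 207 fell; without control replicate 2, 185 rose and 363 fell; and without cold replicate 2, 1597 genes were higher, where the lone library was assumed to vary like the other group. DESeq2 gave 1697 higher and 1397 lower. Among the genes named above, GOLS3 lost the call without either control library, RVE2, COR15A, SEN1 and MLP329 without either cold library, ELIP2 without control replicate 1, and AT3G02480 without either cold library or control replicate 1.

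By list, 13 of 23 COR and LEA genes rose in polysomal RNA and 1 fell, LEA7 at −4.90 (SE 0.284); adjusted over the list alone 15 rose and 2 fell (camera adjusted p = 8.73e-12; adjusted p = 0.448 with an estimated correlation). Of 22 ribosome biogenesis genes 14 rose and 0 fell, or 21 and 0 adjusted over the list alone (camera adjusted p = 6.07e-15; adjusted p = 0.448 with an estimated correlation). FIB2 rose by 3.11 (SE 0.542) and the pre-rRNA processing factor gene SWA1 by 2.502 (SE 0.391). Of 19 flavonoid genes 7 rose and 0 fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 3.20e-07; adjusted p = 0.448 with an estimated correlation). CHS went from 68.1 ± 17.8 to 804 ± 308 CPM, and the flavonol regulator MYB111 rose by 3.46 (SE 0.387). Of 22 cold regulators 4 rose and 0 fell, or 5 and 0 adjusted over the list alone (camera adjusted p = 4.43e-04; adjusted p = 0.448 with an estimated correlation). Among them were CBF2 with a rise of 2.90 (SE 0.439) and its downstream repressor gene RAP2.1 with 3.10 (SE 0.292). CBF1 and CBF3 measured 0.60 (SE 0.984) and 0.66 (SE 0.392) and did not pass. Of 22 sugar, starch and proline genes 6 rose and 1 fell, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.0057; adjusted p = 0.448 with an estimated correlation). Sucrose synthase SUS1 rose by 3.88 (SE 0.573), and the proline synthesis gene P5CS1 was at −2.003 (SE 0.412). Of 24 clock genes 3 rose and 0 fell, or 7 and 0 adjusted over the list alone, with CCA1 up by 2.304 (SE 0.291) (camera adjusted p = 4.70e-05; adjusted p = 0.448 with an estimated correlation). The control polysome libraries lay apart in clock genes, with evening-phased minus morning-phased medians of 0.36 and −1.77 on the log2 CPM scale in replicates 1 and 2, against −1.15 and −0.89 in the cold polysome libraries. The calls of FIB2 and P5CS1 were lost without either control library and those of SUS1 and CCA1 without control replicate 1. The counts of 0 falls by edgeR in these lists corresponded to at most 1 gene at an unadjusted p under 0.05 and at most 1 by DESeq2.

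Of 26 photosynthesis genes 0 rose and 2 fell in polysomal RNA, 8 adjusted over the list alone, with LHCB1.4 at −1.70 (SE 0.3) and LHCA4 at −1.58 (SE 0.329) (camera adjusted p = 8.40e-07; adjusted p = 0.448 with an estimated correlation). Of 21 genes of cell expansion 0 rose and 3 fell, 3 adjusted over the list alone, with the expansin gene EXPA8 at −3.28 (SE 0.576) and PIF4 at −2.32 (SE 0.243) (camera adjusted p = 0.00155; adjusted p = 0.448 with an estimated correlation). Of 23 cytosolic ribosomal protein genes 0 passed by edgeR, whether adjusted over all genes or adjusted over the list alone, but the list was called (camera adjusted p = 1.30e-06; adjusted p = 0.448 with an estimated correlation). RPS5B measured 1.34 (SE 0.337, adjusted p = 0.0624) and RPL9B at 1.22 (SE 0.328, adjusted p = 0.0728), both past the threshold by DESeq2. At an unadjusted p under 0.05 by edgeR 18 of the list were higher, and DESeq2 called 14 higher. Of 22 m6A genes 3 rose and 0 fell, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0128; adjusted p = 0.448 with an estimated correlation): ECT3 by 1.54 (SE 0.325), MTA by 1.13 (SE 0.197) and MTB by 1.02 (SE 0.217). ECT2 and ECT4 at 0.68 (SE 0.294) and 1.28 (SE 0.31), FIP37 at 0.20, VIR at −0.15, HAKAI at 0.45, ALKBH9B at −1.06 (SE 0.292) and ALKBH10B at 0.71 (SE 0.25) did not pass by edgeR over all genes. DESeq2 called 5 genes of this list higher. At an unadjusted p under 0.05 by edgeR 2 m6A genes were lower and by DESeq2 0, and the photosynthesis and cell expansion lists had 0 higher by either. The calls of MTA, MTB, ECT3, LHCB1.4 and LHCA4 were each lost without control replicate 1 and without control replicate 2, and that of EXPA8 without cold replicate 1.

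The other lists were not called in polysomal RNA by camera. Of 20 abscisic acid genes 1 rose, the receptor gene PYL6 by 1.79 (SE 0.264), and 4 fell, among them HAI1 at −2.71 (SE 0.442) and ABF3 at −2.06 (SE 0.307); 4 and 8 passed adjusted over the list alone (adjusted p = 0.109). Of 16 heat shock genes HSP90.2 rose by 1.86 (SE 0.295) and MBF1C was at −2.07 (SE 0.413), and 4 and 2 passed adjusted over the list alone (adjusted p = 0.958; the median was −0.24 and the camera direction was up). Of 8 cold RNA-binding proteins 1 rose, CSP1 by 1.31 (SE 0.281), also 1 adjusted over the list alone (adjusted p = 0.055, and 2.37e-04 without control replicate 1). Of 19 lipid genes 0 passed by edgeR, with 4 higher and 4 lower adjusted over the list alone (adjusted p = 0.852). LTP4 measured −3.33 (SE 0.762), ADS1 −2.62 (SE 0.612) and DGAT1 1.48 (SE 0.428, adjusted p = 0.0839), all past the threshold by DESeq2. That tool called 4 higher and 4 lower, against 5 and 4 at an unadjusted p under 0.05 by edgeR. Of 16 root markers 0 passed over all genes or adjusted over the list alone (adjusted p = 0.0706, and 0.00677 without cold replicate 1). TIP2;3 at −3.29 (SE 0.831) and PYK10 at −1.35 (SE 0.355) were the 2 genes past the threshold by DESeq2, and 3 were lower at an unadjusted p under 0.05 by edgeR. The 2 measured floral organ markers, PI at −1.003 (SE 0.676) and SEP3 at −0.31 (SE 0.465), did not pass by edgeR, by DESeq2 or at an unadjusted p under 0.05 (camera adjusted p = 0.572). Without either control library the calls of PYL6, HSP90.2, MBF1C and CSP1 were lost, without control replicate 2 that of HAI1, and without cold replicate 1 that of CSP1.

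Total and polysomal mRNA changed in similar directions. Across 18668 genes tested in both, 494 rose in both, against 101.8 for independent lists of these sizes, and 415 fell in both, against 92.4. Only 12 of 921 genes called in both had opposite signs. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.644 and a Spearman correlation of 0.644, and 74.5% had the same sign. The Pearson value was 0.496 without cold polysome replicate 1 and 0.506 without control polysome replicate 2.

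**Figure D2:**
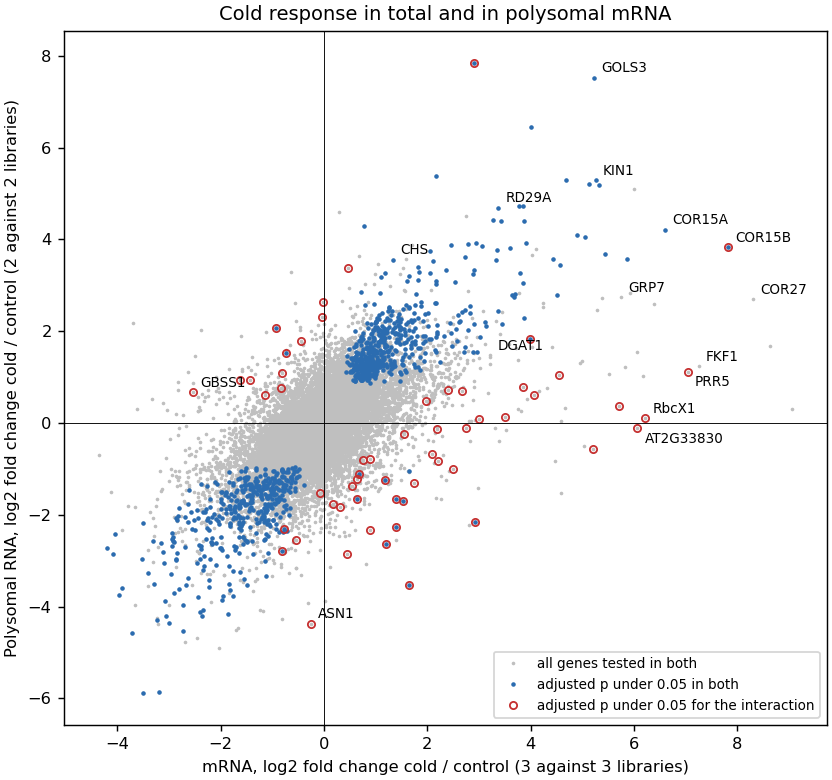
Log2 fold change of each gene in the cold in total mRNA (x axis, 3 against 3 libraries) and in polysomal RNA (y axis, 2 against 2), with genes past an adjusted p of 0.05 in both in blue and genes past it for the interaction ringed in red. KIN1 lies at 5.26 and 5.29, whereas RbcX1, PRR5 and AT2G33830 lie at 6.22, 7.04 and 6.06 on the x axis and low on the y axis.

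Translational efficiency (TE) was taken as the polysomal change beyond the mRNA change. The genes named for the largest falls in TE took a larger share of reads (CPM) in the control polysome than in the control mRNA libraries. AT2G33830 had a TE change of −6.24 (SE 0.783, adjusted p = 0.0206, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), RbcX1 of −6.18 (SE 0.634), and PRR5 of −5.99 (SE 0.808). The thioredoxin gene WCRKC1 was at −5.86 (SE 0.554), AT3G62550 at −5.39 (SE 0.627), the cytochrome P450 gene CYP81D11 at −5.23 (SE 0.588), the co-chaperone gene Fes1B at −5.12 (SE 0.697), ASN1 at −4.17 (SE 0.626), COR15B at −4.05 (SE 0.582) and the membrane protein gene RCI2A at −2.22 (SE 0.363). RbcX1 averaged 0.718 ± 0.307 CPM in control mRNA (n = 3) and 86.4 ± 60.0 in control polysomes (n = 2), against 57.8 ± 7.63 and 93.8 ± 0.244 in cold. PRR5 had 0.620, 0.817 and 2.04 CPM in the control mRNA libraries and 176 and 45.9 CPM in the control polysome libraries. TE rose for the starch synthase gene GBSS1 by 3.15 (SE 0.486), the inositol phosphate synthase gene MIPS1 by 2.93 (SE 0.363), the aspartate oxidase gene AO by 2.84 (SE 0.453), the phenylpropanoid gene 4CL3 by 2.59 (SE 0.379). It also rose for the ammonium transporter gene AMT1;2 by 2.29 (SE 0.327), the mitochondrial carrier gene mSFC1 by 2.27 (SE 0.296), the kinase gene CIPK7 by 2.19 (SE 0.247) and the chloride channel gene CLC-B by 2.16 (SE 0.282).

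**Figure D3:**
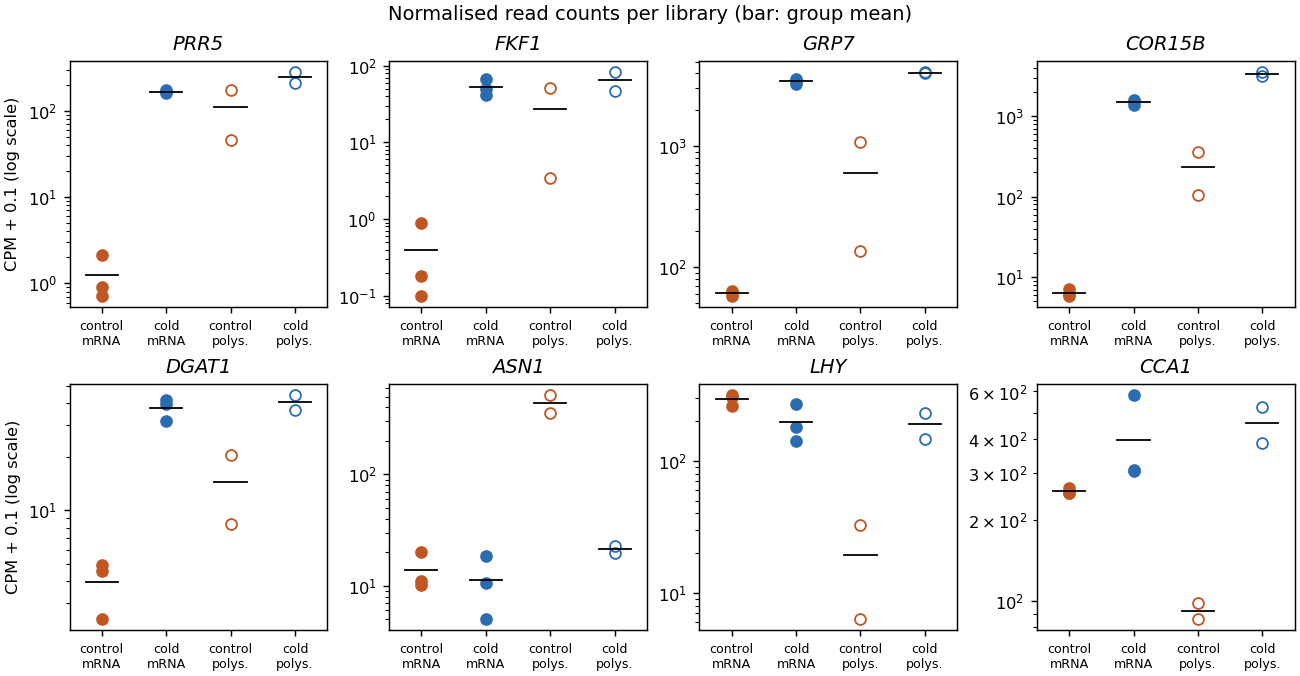
Normalised read counts (CPM + 0.1, log scale) of 8 genes in each library, with control in orange and cold in blue, mRNA filled (n = 3) and polysomal RNA open (n = 2), and a bar at the group mean. PRR5 is at 0.620 to 2.04 CPM in control mRNA and at 176 and 45.9 CPM in control polysomes, and ASN1 at 10.1 to 20.0 CPM and at 355 and 513 CPM.

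For TE, edgeR called 13 genes higher and 44 lower of 20001 tested, and 963 and 1522 passed an unadjusted p of 0.05. In simulated data this test recovered 1% of 2-fold and 49% of 4-fold changes, so the count is no measure of how many genes differed. In 13 of the 13 and 43 of the 44, the distance between polysomal and total mRNA was larger in the control than in the cold libraries. Its medians on the log2 scale were −2.13 in control and 0.118 in cold for the higher genes and 2.97 and 0.302 for the lower ones. Of the evening- and morning-phased clock genes, 0 were among the higher and 1 among the lower genes. Since the larger distance lay in untreated libraries, these calls cannot be told apart from a difference between the control mRNA and control polysome seedlings. DESeq2 called 195 higher and 314 lower, a higher share of 38.31% in place of 22.81%. Most calls rested on single libraries. The counts higher and lower were 3 and 1 without cold polysome replicate 1, 0 and 13 without control polysome replicate 1 (660 and 943 at an unadjusted p under 0.05 by edgeR), 22 and 115 without control polysome replicate 2, and 21 and 25 without cold polysome replicate 2. They were 1 and 7 without control mRNA replicate 2, 7 and 24, 3 and 13, and 5 and 15 without cold mRNA replicates 1, 2 and 3, and 9 and 32 without control mRNA replicate 3. All 19 named TE calls were lost when at least 1 library was left out.

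By list, flavonoid genes had the lowest camera p for TE, with 1 of 19 past the test, 4CL3, and 7 higher and 0 lower adjusted over the list alone (camera adjusted p = 7.69e-10; adjusted p = 0.774 with an estimated correlation). Ribosome biogenesis genes shifted up (camera adjusted p = 1.12e-06) and photosynthesis genes down (6.25e-06), with 0 of 22 and 1 of 26 members past the test (adjusted p = 0.774 with an estimated correlation for each); the 1 was LHCB1.4 at −3.32 (SE 0.541). Cytosolic ribosomal proteins (0.00215) and heat shock genes (0.00509) shifted up and root markers down (0.0468), with 0 members of each past the test by edgeR (adjusted p = 0.774 with an estimated correlation for each). At an unadjusted p under 0.05, 8 ribosome biogenesis genes, 1 ribosomal protein gene and 4 heat shock genes were higher, and DESeq2 called 1 heat shock gene and 0 of the others. Without cold polysome replicate 1 the ribosome biogenesis list was at 0.16, ribosomal proteins turned down at 0.96 and heat shock was at 0.568. Root markers were at 0.115 without cold mRNA replicate 1, 0.328 without control mRNA replicate 3, 0.356 without cold polysome replicate 2 and 0.0784 without control polysome replicate 2, and heat shock at 0.0784 without the last. The other lists were not called by camera. COR and LEA genes (adjusted p = 0.22) had 0 higher and 2 lower by edgeR, 3 and 4 at an unadjusted p under 0.05, and 2 and 3 by DESeq2. Clock genes (0.756) had 0 and 1 by edgeR, 4 and 7 at an unadjusted p under 0.05, and 2 and 4 by DESeq2. Not called either were cold regulators (0.929), sugar, starch and proline (0.516), lipid (0.533), m6A (0.377), cold RNA-binding proteins (0.585), abscisic acid (0.929), cell expansion (0.779) and floral markers (0.929). These 8 lists had 0 genes past the test by edgeR, at most 6 higher and 4 lower at an unadjusted p under 0.05 and at most 4 higher and 3 lower by DESeq2. Without control polysome replicate 2, clock (6.53e-05), cold RNA-binding proteins (7.05e-04), cold regulators (0.00436) and COR and LEA genes (0.00965) passed. The COR and LEA list also passed without cold mRNA replicate 3 (0.0385) or cold polysome replicate 2 (0.0108), and the sugar list without cold polysome replicate 1 (0.00376). None of the 17 genes named in every comparison passed for TE by edgeR. MTA measured 0.75 (SE 0.213, adjusted p = 0.179), MTB 0.12, FIP37 −0.10, VIR −0.42, HAKAI 0.22, ALKBH9B −0.46 and ALKBH10B 0.58. ECT2, ECT3 and ECT4 measured 0.04, 0.82 and 0.01, and CBF1, CBF2 and CBF3 1.08, 0.76 and −1.18. COR15A measured −2.45 (SE 0.763), RD29A 1.26 (SE 0.564), KIN1 −0.04 (SE 0.38) and DGAT1 −1.80 (SE 0.526, adjusted p = 0.196). GRP7, of the cold RNA-binding list, measured −3.08 (SE 0.876) and did not pass either.

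m6A peaks lay mostly in coding sequence, most densely at its end, and in 3′ UTRs in both conditions. The cold lists held 21736 ± 5770 peaks in 12742 ± 1753 genes and the control lists 25973 ± 2285 peaks in 14096 ± 827 genes (SD, n = 3 per group; exact permutation p = 0.2 and 0.3, two-sided; the smallest possible is 0.1). The difference in peak number was −16.3%, and −4.08% without cold list 3 and −25.8% without cold list 2. Peak summits lay in coding sequence in 56.4% ± 7.38 of cold and 63.0% ± 1.94 of control peaks and in 3′ UTRs in 38.1% ± 8.13 and 31.4% ± 1.14 (exact permutation p = 0.2 for each, 0.9 after Benjamini-Hochberg adjustment over the 9 classes). Cold list 3 had 47.4% in 3′ UTRs, and without it the difference of 6.75 percentage points in 3′ UTRs became 2.1 and that of −6.61 in coding sequence became −2.37. Summits within 100 nt of a stop codon made up 26.0% ± 3.01 and 24.9% ± 0.887 (exact permutation p = 0.6), and those within 100 nt of a start codon 3.80% and 3.88%. The order of the parts depended on peak strength. With a q of at most 0.05, 56.0% of cold and 49.6% of control summits lay in 3′ UTRs and 39.15% and 45.6% in coding sequence. Among peaks with a −log10 q of at least 5, on average 853 per cold and 1043 per control list, 73.2% and 72.7% lay in 3′ UTRs.

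**Figure D4:**
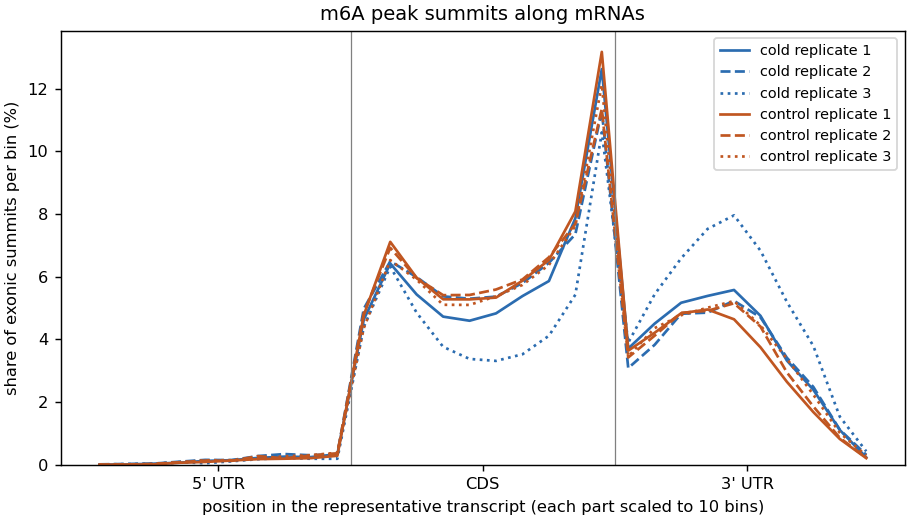
Share of exonic m6A peak summits in each of 10 bins of the 5′ UTR, coding sequence and 3′ UTR (y axis, percent; x axis, position along the representative transcript), 1 line per list. All 6 lists have their highest bin at the end of the coding sequence, and cold list 3, with 47.4% of its summits in 3′ UTRs, lies above the others in the 3′ UTR. Bins of different parts differ in length.

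Known m6A contexts were more frequent around summits than at random exonic positions in all 6 lists. RRACH, the general methylation motif, lay within 50 nt of 76.8% ± 0.444 of cold and 77.5% ± 0.744 of control summits, against 72.4% and 72.3% of random exonic positions (R is A or G, H is A, C or U, Y is C or U). URUAY, a plant m6A context, lay near 32.0% ± 2.09 and 29.6% ± 1.16, against 26.5% and 26.6%, and UGUAA near 15.6% ± 2.03 and 13.7% ± 0.763, against 9.34% and 9.45%. The lowest summit share over the 6 lists was 76.5% for RRACH, 28.4% for URUAY and 12.9% for UGUAA, and the highest random share 72.8%, 26.9% and 9.87%. At random positions of the same transcript part the mean shares were 31.3% and 29.5% for URUAY, within 1 percentage point of those at summits, and 13.0% and 11.8% for UGUAA. In control list 1 URUAY was less frequent at summits, at 28.35%, than at these positions, at 28.91%. Among peaks with a −log10 q of at least 5, URUAY was near 46.7% and 46.3% of summits and UGUAA near 27.8% and 26.0%, against 41.9% and 40.0%, and 20.9% and 19.8%, at random positions of the same transcript part.

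In the deposited lists, which reach down to an unadjusted p of about 0.05, 9473 of 14046 expressed genes carried a peak in all 6. With equal numbers of top peaks per list 5285 did, and 1121 had none. Any pair of lists shared a median of 89.3% of their genes within a condition and 88.2% between conditions. Of 14046 genes above the expression floor, 13531 had a peak in at least 1 list and 515 in 0 of 6. The 515 take in organelle and other-named features above the floor, to which no peak could be assigned. By the rule of 3 lists against 0, 11 genes gained and 118 lost a peak in the cold. The gained genes included LUX, of the evening complex of the clock, RAP2.6, an ERF transcription factor, the chloroplast gene-expression proteins PTAC15 and OTP81, and AT1G47400, the only one with at least 20 CPM in both groups; all but AT1G47400 were chosen after their values were seen. AT1G47400 cleared 20 CPM only as a group mean. In replicates 1, 2 and 3 it stood at 52.6, 18.8 and 1.18 CPM in control mRNA and 64.9, 41.6 and 8.37 in cold mRNA. AT1G47400 had summits in coding sequence on chromosome 1 of TAIR10, at 17385900, 17385901 and 17385842 in cold lists 1, 2 and 3, and a −log10 q of 0 in cold list 1. The lost genes named by rule were VPS54, the non-coding AT2G24755, SKL1, RING (AT4G19700) and TPD1. SKL1, a shikimate kinase-like chloroplast protein, had control summits on chromosome 3 at 9912376, 9912370 and 9912375, in coding sequence 60, 54 and 59 nt before the stop codon. DGAT1 was in neither group, and its control mRNA of 3.87 ± 1.33 CPM, against 37.5 ± 5.23 in cold, lay below the floor of 5 CPM. Its peak in the 3′ UTR on chromosome 2, at 8429392 to 8429815 in cold list 1 with its summit at 8429613, 160 nt after the stop codon, was in 3 of 3 cold lists and in control list 3 alone (8429582 to 8429715). Counts depended on the lists used. Without cold list 3, 45 genes were gained, and 20, 25 and 36 were without control lists 1, 2 and 3. Lost genes numbered 271, 322 and 229 without cold list 1, cold list 2 and control list 1. At equal numbers of top peaks per list, 96 genes were gained and 95 lost. The counts of 11 and 118 are thus no measure of a net loss in the cold.

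As sets, genes that gained a peak had higher mRNA in the cold and genes that lost one had lower mRNA. The 11 gained genes had a median mRNA change of 1.25, above all 10000 expression-matched random sets, and 6 of them rose (camera adjusted p = 3.35e-06; adjusted p = 0.072 with an estimated correlation). Among the risen were OTP81 by 2.33 (SE 0.242), RAP2.6 by 1.60 (SE 0.43) and PTAC15 by 1.13 (SE 0.217). The 118 lost genes had a median of −0.73, below all random sets, and 52 of them fell (camera adjusted p = 4.58e-14; adjusted p = 0.00681 with an estimated correlation). Genes with a peak in all 6 lists had a median of 0.09, at percentile 100 (camera adjusted p = 0.00417, and adjusted p = 0.0422 with an estimated correlation). They made up most of the pool, so random sets shared most of their genes. The central 95% of random medians spanned only 0.045 to 0.06, so percentile 100 here marks a small shift. Genes assigned no peak had a median of 0.07, at percentile 99.97 (camera adjusted p = 0.752). With equal numbers of top peaks per list, 96 genes were gained with a median of 0.13, at the 86.5th percentile (camera adjusted p = 0.0371), and 95 were lost with a median of −0.43, at percentile 0 (camera adjusted p = 2.40e-08). In polysomal RNA the median was 0.48 for gained genes (camera adjusted p = 0.00235; adjusted p = 0.251 with an estimated correlation) and −0.49 for lost genes (camera adjusted p = 3.11e-06; adjusted p = 0.0464 with an estimated correlation). The gained median was 1.67 without control polysome replicate 1, 0.94 without cold polysome replicate 2 and 0.30 without cold polysome replicate 1.

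**Figure D5:**
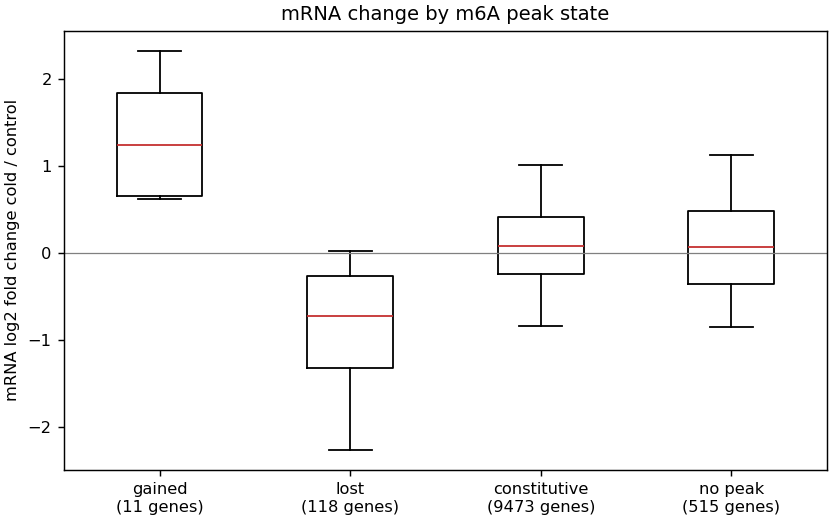
Log2 fold change of mRNA in the cold (y axis, 3 against 3 libraries) for genes above 5 CPM that gained (11), lost (118), kept in all 6 lists (9473) or were not assigned (515, organelle features included) an m6A peak. Boxes span the quartiles with the median, and whiskers reach the furthest gene within the 5th to 95th percentile; the medians are 1.25, −0.73, 0.09 and 0.07.

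For TE, medians were −0.43 in gained, 0.13 in lost, −0.01 in constitutively marked genes and −0.29 in genes assigned no peak, at the 1.15th, 99.8th, 75.7th and 0th percentile of the matched random sets. By construction the last set takes in organelle features above the floor. None of these sets was called by camera (adjusted p = 0.122, 0.0503, 0.268 and 0.0503). The median of gained genes was 0.04 without cold polysome replicate 2 and 0.08 without control polysome replicate 1, and that of lost genes −0.004 and −0.007 without the same libraries. Without control mRNA replicate 3 they were −0.045 and 0.075. The gained median was −0.21 without cold mRNA replicate 1, −0.85 without cold polysome replicate 1 and −0.67 without control polysome replicate 2.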

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

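The tests of clock phase and of dark-inducible genes were chosen only after clock genes, ASN1 and SEN1 had been seen among the largest changes, with their predictions written before the test values were seen. The demand that their bounds hold without each library was added after these values were seen. For 13 genes the polysomal response to cold was higher than the mRNA response and for 44 it was lower, by a test of the difference itself. Cold mRNA replicate 3 had 82.2% of its reads without a unique alignment and 9.19% outside genes, tallies that enter no comparison, above the highest control mRNA values of 66.3% and 5.68%. Its gene counts held 22.1% of chloroplast and mitochondrial reads.

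In control libraries the median log2 ratio of polysomal to total mRNA was 1.84 above that of all genes for 11 evening-phased genes, with 11 of 11 above. It was 0.799 above without control polysome replicate 1 and 2.88 above without control polysome replicate 2. For 9 morning-phased genes it was −0.207 from that of all genes, with 2 of 9 above (−0.568 without control mRNA replicate 1, −0.585 without control polysome replicate 2 and −0.0764 without control mRNA replicate 3). The gap of 2.05 was 1.00 without control polysome replicate 1 and 3.47 without replicate 2, and evening minus morning medians were 0.36 and −1.77 in these libraries, against −2.91, −2.94 and −4.24 in control mRNA. LHY, a morning gene, stood at 315, 261 and 304 CPM in control mRNA and at 6.26 and 32.5 CPM in control polysomes, whereas the evening gene TOC1 stood at 17.2, 13.6 and 12.4 CPM and at 107 and 24.95 CPM. A candidate explanation is that control seedlings for mRNA and for polysomes were collected at different times of day, for which a gap of at least 1 with opposite signs was predicted. For lower polysome loading of evening transcripts in the cold, a control ratio near that of all genes and a low cold ratio were predicted. Neither was found, since their ratio went from 1.84 to 0.098 above that of all genes. That prediction took an average control level for granted and did not cover a fall from a high one. For this fall, lower loading in the cold and different collection times cannot be told apart. The gap of 2.05 lay within untreated libraries, so an effect of cold could account only for its absence in the cold, not for the gap.

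Among genes known to be induced by darkness, ASN1 stood at 20.0, 10.95 and 10.1 CPM in control mRNA and at 355 and 513 CPM in control polysomes, and SEN1 at 17.36, 9.07 and 17.7 CPM and at 779 and 298 CPM. For 6 other dark-inducible genes the ratio of polysomal to total mRNA in control libraries had a median 1.01 above that of all genes (range 0.345 to 3.1, 6 of 6 above), against a bound of 1 set beforehand that was missed without control polysome replicate 1 (0.887) or control mRNA replicate 3 (0.793). Less light for the control polysome seedlings before collection, and lower polysome loading of these transcripts in the cold, cannot be told apart on these values, since the 6 values in cold libraries ran from −1.09 to 1.75 around a median of 0.418. For lower loading, a control median near that of all genes and a low cold median were predicted, and neither was found. The excess of 1.01 lay within untreated libraries, so an effect of cold does not account for the excess itself.

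Of 11 genes that gained an m6A peak 6 rose in mRNA, and of 118 that lost one 52 fell. Their median mRNA changes lay at percentile 100 and percentile 0 of 10000 expression-matched random sets. A candidate explanation is that detection of a peak follows transcript level, for which both extremes were predicted. With equal numbers of top peaks per list the medians were 0.13 (percentile 86.5, camera adjusted p = 0.0371) in gained and −0.43 (percentile 0) in lost genes, and by the rule of 2 of 3 lists 0.61 (percentile 100) and −0.55 (percentile 0). An effect of the mark on transcript level stays open and was not tested, since input coverage of the immunoprecipitations was not analysed here.

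The 6 mRNA libraries form 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4949 genes and the highest other split 0 by edgeR, where the other splits had 39 to 1031 genes at an unadjusted p under 0.05. Each other split mixed cold and control libraries, so the cold response entered the spread within its groups. The 0 is thus no measure of false calls. The 6 peak lists also form 10 splits, again too few. The real split gave 129 gained and lost genes and the highest other 108. Of the 129, 11 were gained and 118 lost. The larger side of the other 9 splits held 11 to 106 genes, more than 11 in 8 of them. In none of these 9 was the side with cold list 3, the shortest list, the larger. The excess of lost over gained genes thus cannot be told apart from the short list. For the mRNA libraries and for the peak lists, 1 of the 10 splits, the real one, gave as many.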

How the results depend on the processing

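Tests chosen only after the data were seen were those with a q of at most 0.05, with exons on either strand, with motifs on stronger peaks or against the same transcript part, and the list tests and the polysome to mRNA ratios without single replicates. Of 58 called named genes in mRNA, 21 lost the call under at least 1 alternative, as did 25 of 40 in polysomal RNA and 19 of 19 for TE, and none reversed. Leaving out a replicate gave 1424 to 2626 higher and 1148 to 2218 lower genes in mRNA, 141 to 1597 and 207 to 1044 in polysomal RNA, and 0 to 22 and 1 to 115 for TE, where fewer samples lower the power. The correlation of mRNA and polysomal changes ran from 0.496 to 0.685. Library totals gave 1361 higher genes in mRNA, and 8 higher and 27 lower for TE. DESeq2 gave 1697 and 1397 in polysomal RNA and 195 and 314 for TE. Named genes that had not passed also gained calls. DESeq2 called 8 of 18 such genes in polysomal RNA and 10 of 38 for TE. In polysomal RNA the fit of all 10 libraries and the replicate block each called 10 of these 18. A fit of all 10 libraries gave 2150 and 1766 in polysomal RNA, and no count filter gave 1170 higher. With an estimated correlation 3 lists were called in mRNA, 0 in polysomal RNA and 0 for TE, and fry called 11 in mRNA, 0 in polysomal RNA and 0 for TE, against 9, 10 and 6 by camera. The ribosomal protein list turned down for TE without cold polysome replicate 1 (adjusted p = 0.96, against 6.76e-12 without cold polysome replicate 2). The ratio of polysomal to total mRNA of evening clock genes in the cold ran from −0.132, without cold mRNA replicate 2, to 0.256. Apart from the loss of samples, the cause was not tested.

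The replicate numbers did not pair the mRNA libraries. Deviations of same-numbered mRNA libraries correlated at −0.034, −0.016 and 0.223, not each best with its own number. Those of same-numbered polysome libraries correlated at 0.465, but with only 2 pairs a pairing could be neither shown nor excluded. With the replicate number as a block, 2247 genes were higher and 2129 lower in mRNA, 2199 and 2309 in polysomal RNA, and 47 and 76 for TE. The list calls that changed under the block were abscisic acid in mRNA (adjusted p = 0.0111), and in polysomal RNA cold RNA-binding proteins (0.0438), abscisic acid (0.047) and root markers (0.0478); no other list call changed. For TE the sets of genes that lost a peak (0.00521) and of genes without a peak (0.0225) also passed camera.

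For m6A, the difference of cold and control in summits near a stop codon was −4.12 percentage points among peaks with a −log10 q of at least 5, −0.967 with a q of at most 0.05, −0.704 with equal numbers of top peaks, −0.0301 with a window of 50 nt and −0.337 without cold list 3, and ran from −0.337 to 2.67 over the lists left out. Leaving out a list gave 14 to 45 gained and 135 to 322 lost genes. Lost genes numbered 23 at a −log10 q of at least 5, and gained genes 96 with equal numbers of top peaks. Gained and lost were 52 and 289 by the rule of 2 of 3 lists, 1 and 14 at 20 CPM, which leaves fewer genes, 36 and 184 with a q of at most 0.05, and 53 and 412 with merged regions. With equal numbers of top peaks the mRNA median was 0.125 in gained genes and −0.019 in genes without a peak, and the TE median 0.065 in gained, −0.001 in lost and −0.032 in constitutively marked genes. By the rule of 2 of 3 the TE median of gained genes was 0.007. Leaving out a replicate gave −0.85 to 0.08 for gained and −0.007 to 0.17 for lost genes, with 0.041 for gained genes without cold polysome replicate 2 and 0.08 without control polysome replicate 1. Summits exceeded random exonic positions by 21 percentage points for URUAY and 17.2 for UGUAA among peaks with a −log10 q of at least 5. Against the same transcript part the excess among all peaks was 0.418 and 2.23. For the stronger peaks that comparison was 46.7% and 46.3% against 41.9% and 40.0% for URUAY in cold and control. For UGUAA it was 27.8% and 26.0% against 20.9% and 19.8%. Beyond the filters themselves, the cause was not tested. The depth behind each peak list was not given in the sources used here, and the depth of cold mRNA replicate 3, at 3.28 in units of 1e+06, limits its low genes.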

Other observations

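The look at dark-inducible genes was chosen only after ASN1 and SEN1 had been seen among the largest changes. Of 6 other dark-inducible genes, DIN3 and DIN9 fell in polysomal RNA. DIN3, a subunit gene of the branched-chain keto acid dehydrogenase, was at −1.42 (SE 0.223, adjusted p = 0.0272, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) and DIN9, a mannose-6-phosphate isomerase gene, at −2.52 (SE 0.454, adjusted p = 0.0329). DIN9 also fell in total mRNA, by 1.14 on the log2 scale (SE 0.328, adjusted p = 0.0346). DIN10, a raffinose synthase family gene, stood at 496 and 164 CPM in control polysomes and at 97.7, 37.3 and 9.75 CPM in control mRNA, and its polysomal change of −2.55 (SE 0.723, adjusted p = 0.0818) did not pass. DIN4, DIN2 and DIN11 measured −1.16, 0.18 and 0.45 in polysomal RNA and did not pass.

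The 515 expressed features assigned no m6A peak had a median TE change of −0.29, with quartiles of −0.93 and 0.17, at percentile 0 of 10000 expression-matched random sets, whose central 95% of medians ran from −0.08 to 0.02. Their polysomal change had a median of −0.30 over 483 genes tested (camera adjusted p = 0.0428; adjusted p = 0.251 with an estimated correlation), and of −0.12 with equal numbers of top peaks (camera adjusted p = 0.261). For TE, camera gave an adjusted p of 0.0503, and an adjusted p = 0.405 with an estimated correlation, so the set was not called. With equal numbers of top peaks per list the TE median of genes without a peak was −0.08. These sets take in organelle features above the floor, since peaks were placed on nuclear genes only. Chloroplast and mitochondrial genes made up 6.28% to 22.1% of gene counts in mRNA libraries and 0.153% to 0.437% in polysome libraries. The medians are therefore not a trait of unmarked nuclear transcripts alone, and the part of the organelle features in them was not tested.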
